A study of Drosophila melanogaster with 2 samples.

How the data were processed

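ChIP-seq against GFP was done by the submitters on sonicated chromatin of whole wandering larvae of the third instar, pooled over both sexes, from a line with tai fused to eGFP, per the labels. The labels give 2 biological replicates of 1 group, numbered 1 and 3, each from its own biosample. The files are peak lists in narrowPeak layout on the builds dm6 and dm3. Per the text records deposited with them, each replicate's list and the pooled list hold peaks and background regions called on alignments with the same control alignment, the pooled list comes from both replicates' alignments, and the IDR list was derived from all 3. The aligner, the peak caller and its settings are not given in the sources used here. The control and the reads were not analysed here. Since both replicates share 1 control, part of their overlap may come from it.

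The signal value of each peak is the authors' own, relative to the control, on a scale that the sources used here do not state. The −log10 q value in the deposited lists was read only to describe them. Across regions it rose with signal in replicate 1 (Spearman's rho 0.94) and fell with it in replicate 3 (rho -0.52) and in the pooled list (rho -0.39), so peaks were ranked by signal. The IDR list on dm6 was exactly the 2591 regions of highest signal in the pooled list. Depth per replicate is unknown, so the precision given is that of counts of peaks, with 95% Clopper-Pearson intervals that cover counting error only. Within the deposited lists 12 IDR peaks repeated the interval of another peak with its own summit, and they were kept.

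Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes, TSSs and exons came from the Ensembl release 115 annotation of BDGP6.54 and sequence from RefSeq's copy of the same assembly, which has the arms of dm6. Coordinates are 1-based on dm6. The dm3 lists were compared only by counts, shares and signals, and no coordinate was converted between builds. Main results used arms 2L, 2R, 3L, 3R, 4 and X, and peaks on the mitochondrial genome are given apart.

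Replicates were compared by the overlap of their strongest peaks, as many as there were IDR peaks on the arms, by 1 bp or more, against 1000 circular shifts of one list. Spearman's rho used the signal of the strongest overlapping peak in each replicate and has no p-value. The promoter share counted summits within 500 bp of a protein-coding TSS against 1000 circular shifts along each arm, one-sided. A gene counted as having a peak when an IDR summit lay within 1000 bp of any of its TSSs, which held for 1103 of 13945 protein-coding genes. The 25 gene lists and the 20 motifs were fixed before the data were examined. Lists were tested by Fisher's exact test, two-sided, against all other protein-coding genes, and again against 10000 random lists matched on gene length and number of TSSs. Motifs within 100 bp of a summit were compared with a window of the same width 1000 bp away by McNemar's exact test, for the 2543 peaks with a free flank. Arms were tested by the exact binomial test against their share of protein-coding genes. P-values were adjusted by the Benjamini-Hochberg method within each family at a threshold of 0.05.

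The genes named in the text were chosen by a rule set before the data were examined. It names tai, EcR and usp, the 20 genes with the nearest TSS within 1000 bp of the strongest arm peaks, up to 4 members of each list with the strongest peaks, and the 5 genes with the most summits, and gives 64 genes. On the way to the 20 genes 16 peaks without a TSS within 1000 bp were passed over. The rule was applied to arm peaks only, which was settled once mitochondrial peaks had been seen to be the strongest. Added after the values were seen were sbb, tied with kirre, the genes nearest to single peaks (cbt, CG9586, Hdc, Adhr), neur as the fifth Notch gene with a peak, Antp, and the genes of densely bound windows (hng3, CG13896, heca, tara, E2f1, InR, tkv and vri), and the 3 mitochondrial genes. Also added then were kibra and CHES-1-like, for their summits per 10 kb.

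Each test was also run on simulated data, after a first look at the real lists. The promoter test called 20 of 20 simulated lists with planted summits and 1 of 20 without. A planted overlap of 50% was recovered as 50.7%. For a list of the size of ecdysone response, odds of 8 were called in 42 of 50 runs and odds of 4 in 26 of 50, and with no effect 1 list was called over 50 runs of 25 lists. In those 50 runs the test against matched lists gave an unadjusted permutation p under 0.05 for 13 lists. Outside the planted list, simulated genes all had the same chance of a peak whatever their length or number of TSSs. These rates therefore need not hold for the real lists. Motifs planted in 5% of windows were called in 59 of 60 runs and unplanted ones in 0 of 60. These calls used 0.05 divided by the number of motifs, not the Benjamini-Hochberg method used on the real motifs. Smaller differences, such as that of DRE (2.44% of summits and 0.629% of flanks), were not simulated. Simulated summits and flanks had the same base composition, unlike the real ones, so false calls that come from composition were not measured. The arm test called at least 1 arm in 7 of 100 runs without a difference.

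The alternatives set before the data were examined were other distances, overlap rules, windows, backgrounds, the 50% of peaks with the highest signal, the dm3 lists, and each replicate's own top peaks in place of the IDR list, which stand for leaving out the other replicate. Motifs were also compared with up to 1000 distinct permutations of themselves. A motif passed there at an unadjusted two-sided permutation p, since short motifs have few permutations, and their number was raised after a first run with fewer, under which more motifs had passed, had been seen. Chosen after seeing the data were the lower-ranked pooled regions as background, only peaks found in both replicate lists, only genes with a pooled region near a TSS, tai left out of every list, and peaks within 10 kb of tai left out.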

Results

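Chromatin immunoprecipitation and sequencing (ChIP-seq) was done on whole wandering larvae of the third instar, of both sexes, from a Drosophila melanogaster line that carries tai fused to eGFP at its C terminus. tai (Taiman) encodes a coactivator of the ecdysone receptor with bHLH and PAS domains. The antibody was against GFP, so peaks mark DNA recovered with the tagged protein. There was 1 group with 2 biological replicates, numbered 1 and 3, and no second stage, tissue or genotype to compare with. The deposited peak lists held 29999 regions for replicate 1, 30000 for replicate 3 and 30000 for the pooled replicates, on the dm6 build (release 6 of the fly genome). The list that passed the authors' irreproducible discovery rate (IDR) step held 2591 peaks. Read depth is unknown from these lists, so no interval that needs it is given. The signal value quoted for a peak is the authors' own and serves only to rank and describe peaks within a list.

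Of the IDR peaks, 2567 lay on the 6 main chromosome arms and 24 on the mitochondrial genome, and the arms are described here. The strongest arm peak (2L, 480910 to 481288, signal 1109) lay in an intron of ush, 1357 bp from the nearest protein-coding TSS, that of cbt. The next (2L, 6612521 to 6612876, signal 1023) lay in an intron, 1017 bp from the nearest TSS. Among the 20 genes named for the strongest peaks near a TSS, CG1888 came first (2R, 9547005 to 9547372, 5' UTR, signal 819). It was followed by ph-p, a Polycomb group gene (X, summit 2137320, intron, signal 736), gish, a casein kinase gene (3R, summit 16280745, intron, signal 713), and Atat, a tubulin acetyltransferase gene (3L, summit 9426844, signal 709). Sox14, an ecdysone-induced transcription factor gene, had a peak 255 bp from its TSS (2R, 23978412 to 23978759, signal 637). fkh, a forkhead factor of the salivary gland, had a peak 248 bp from its TSS (3R, 28585388 to 28585617, signal 471). The others of this group were CG8360, Lk6, CG9663, LPCAT, larp, mRpL41, Chro, CG5611, Trp1, CG18549, aralar1, Gapdh2, HmgZ and Pi3K21B, with signals from 421 to 703. Over all arm peaks the median signal was 89.1, with quartiles of 73.4 and 125.

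The only comparison that the design gives is between its replicates, and it asks how far the same regions were found in both. The strongest peak, in ush, and the next 2 ranked in the same order in both replicates. Of the 20 genes named for their signal, 18 had their peak within the top 150 of both lists. The peaks at mRpL41 (rank 20 in replicate 1) and Pi3K21B (rank 52 in replicate 1) overlapped no region at all in the replicate 3 list, though replicate 3 had another summit near a TSS of Pi3K21B, at rank 2488. Among the 62 named genes with a summit near a TSS, 53 had that peak in the top 2567 of both replicates. Desat1, a fatty acid desaturase gene, ranked 706 in replicate 1 and 23097 in replicate 3.

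When each replicate was limited to its 2567 strongest arm peaks, 51.4% overlapped a peak of the other by 1 bp or more (mean of both directions, 1341 and 1299 peaks). With the replicate 3 list shifted in a circle along each arm, 1.49% of replicate 1 peaks overlapped it on average and 2.42% at most. Unshifted, the share in that direction was 52.2%. The mean of both directions set against these shifts gave a permutation p of 0.001 (one-sided, the smallest that 1000 shifts can give). Of the arm IDR peaks, 95.7% overlapped a region in both whole replicate lists, 11 had none in replicate 1 and 100 had none in replicate 3. Of these 100, 51 had their summit within 500 bp of a TSS, compared with 790 of the other 2467 (51.0% and 32.0%, Fisher's exact test, two-sided, p = 0.000125). Spearman's rho of the replicate signals across 2456 IDR peaks was 0.46. Peaks are not independent replicates, and the IDR list was exactly the 2591 pooled regions of highest signal, which limits the range that this correlation covers.

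The share of IDR peaks that stood in the top 2567 of both replicates fell with rank in the pooled list. It was 96% for ranks 1 to 100 (95% Clopper-Pearson interval 90.1 to 98.9) and 84.8% for ranks 501 to 1000 (81.3 to 87.8). It was 16.4% for ranks 1501 to 2000 (13.3 to 19.9) and 6.17% for ranks 2001 to 2567 (4.34 to 8.48). All such intervals cover counting error only. Since the list was chosen on pooled signal, part of this fall follows from how it was made.

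**Figure D1:**
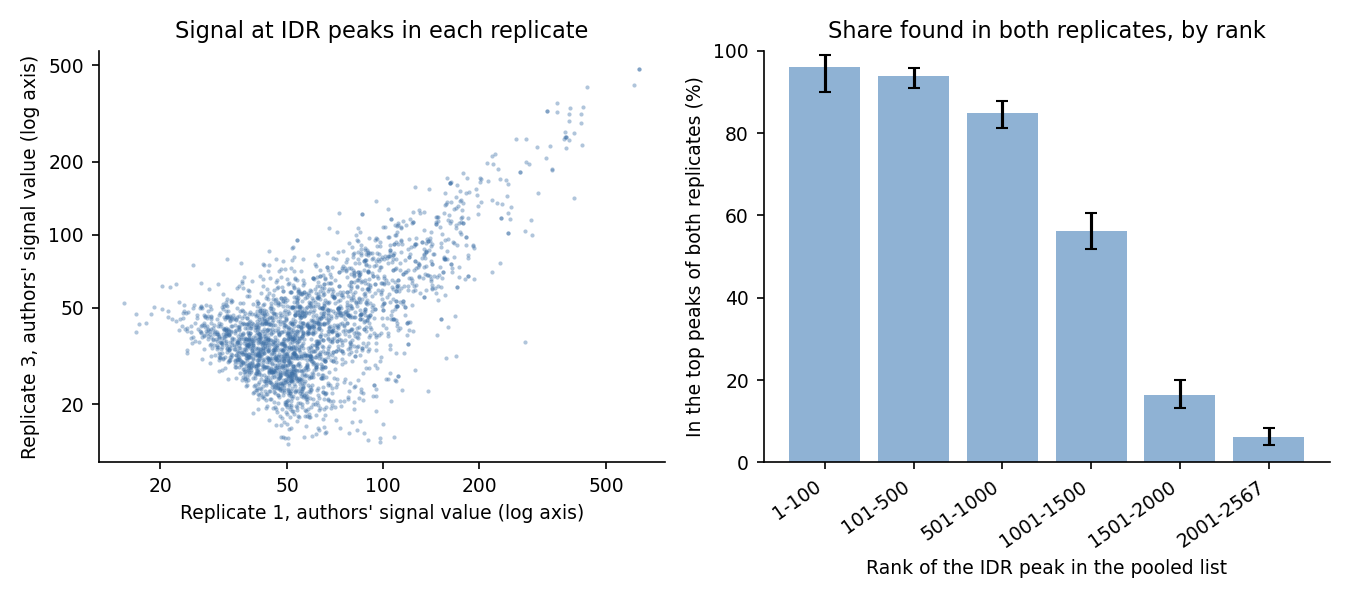
Left, the authors' signal value of the strongest overlapping peak in replicate 1 (x axis, log scale) and replicate 3 (y axis, log scale), with 1 point for each of 2456 IDR peaks. Right, the percentage of IDR peaks in the top 2567 of both replicates by rank in the pooled list, with 95% Clopper-Pearson intervals, which falls from 96% to 6.17%.

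IDR peaks were concentrated at promoters and were nearly missing from coding sequence. The summit lay within 500 bp of a protein-coding TSS in 841 of 2567 peaks, or 32.8% (95% interval 30.9 to 34.6), as at CG8360, Chro, Hsp27 and RpS27A. Shifted positions gave 11.4% on average and 14.2% at most (permutation p = 0.001, one-sided, the smallest possible). The 27407 lower-ranked pooled regions gave 11.5%. Outside promoters, 1144 summits (44.6%) lay in introns, among them the strongest ones at Eip75B, Kr-h1 and grh, compared with 39.1% of shifted positions and 52.7% of lower-ranked regions. Coding sequence held 10 summits (0.390%, compared with 14.1% of shifted positions and 2% of lower-ranked regions), and 3' UTRs held 48 (1.87%, compared with 4.46% and 5.07%), each with permutation p = 0.001 for the lower side against shifted positions. Most of the shortfall in coding sequence was thus shared by the lower-ranked regions. Intergenic summits made up 19.6%, compared with 30.3% and 27.8%. The median distance to a TSS was 1512 bp, and 13.2% of summits lay over 10000 bp away. Replicate 1 alone gave a promoter share of 38.3% and replicate 3 alone 32.0%.

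**Figure D2:**
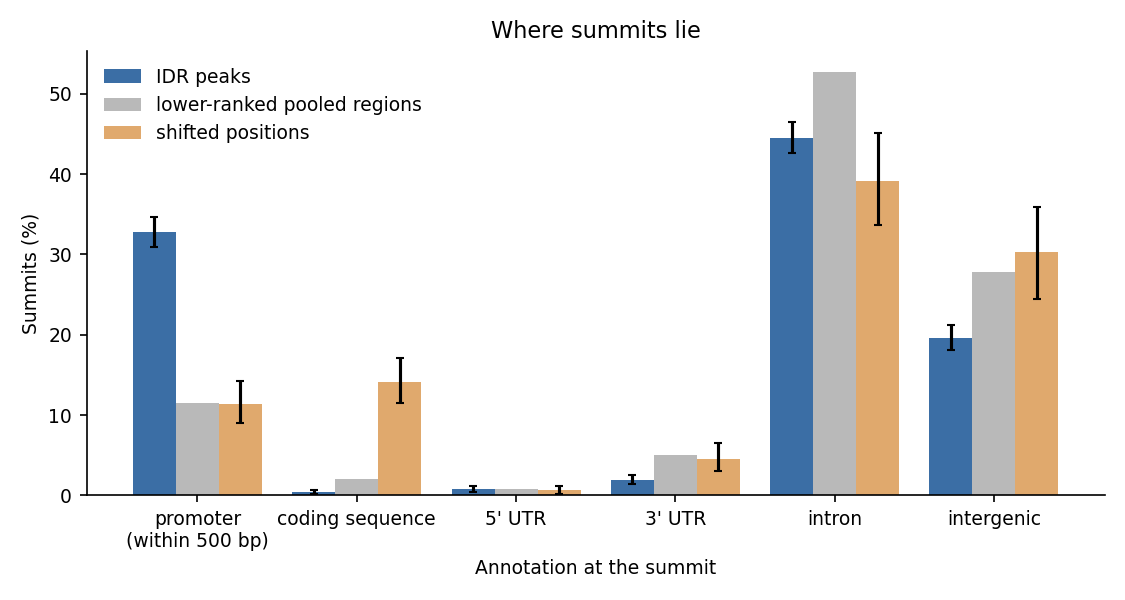
Percentage of summits (y axis) by annotation (x axis) for 2567 IDR peaks with 95% Clopper-Pearson intervals, for 27407 lower-ranked pooled regions, and for shifted positions as the mean of 1000 shifts with their lowest and highest values. The promoter share of IDR peaks was 32.8% and that of shifted positions 11.4%.

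By raw count, the genes with the most IDR summits in the body or within 1000 bp were tai itself and genes of the ecdysone pathway. tai held 31 (2L, 9166778 to 9250211, plus strand), Eip75B, a nuclear receptor gene induced by ecdysone, held 22 (3L, 17950953 to 18064696, minus strand), and EcR, the ecdysone receptor gene, held 16 (2R, 6087873 to 6169087, minus strand). Eip74EF, an ETS factor gene induced by ecdysone, held 15 (3L, 17558672 to 17619325, minus strand). kirre held 13 over 394149 bp (X, 2740384 to 3134532), as did sbb over 79099 bp, which the alphabetical rule for ties left unranked. usp, whose product pairs with EcR, had none. These counts do not allow for length, and summits of overlapping intervals were counted apart. Per 10 kb, tai held 3.63 summits, Eip74EF 2.39, EcR 1.92 and Eip75B 1.90. The shorter genes kibra (2.45) and CHES-1-like (2.41), with 7 summits each, were denser than all of these but tai. The gene that carries the tag led the counts in each replicate too, with 27 summits among the top peaks of replicate 1 (18 in Eip75B) and 30 in replicate 3 (22 in Eip75B). Because the line carries a tagged copy of tai, counts in this gene cannot be read like those of other genes.

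Within these genes the peaks were mostly intronic. The strongest in tai lay at 9211299 (signal 346), and 2 lay just upstream of its TSS, at 9166557 (signal 222), which was 43 bp from the TSS of the neighbouring CG9586, and at 9166760 (signal 182), nearer to that of tai. The strongest in Eip75B, at 18011907 (signal 636), ranked 13 in replicate 1 and 20 in replicate 3, and a second lay 18 bp from one of its TSSs (17999637 to 18000040, signal 149). In EcR the strongest peak was at 6151253 (signal 197) and ranked 648 in replicate 1 and 95 in replicate 3. In Eip74EF the strongest inside the gene or within 1000 bp was at 17590714 (signal 153).

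Genes of the ecdysone response had IDR peaks near their TSSs far more often than other genes. Of the 29 genes on this list, 15 had a summit within 1000 bp of a TSS (51.7%, 95% interval 32.5 to 70.6), compared with 1088 of 13916 other protein-coding genes (7.82%). The odds ratio was 12.6 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.82e-08 over 25 lists). The strongest members were tai (signal 222), Ldh, encoding lactate dehydrogenase (197), Eip63F-1, a calcium-binding protein gene (177), and Eip75B (149). Eip74EF (123), Hr39 (108), EcR (81.7), Hr3 (79.4) and Kr-h1 (67.3) were also among the 15. The Hr3 summit lay nearer to the TSS of Hdc. Random lists matched on gene length and number of TSSs held 7.38 such genes on average, and the call held against them (permutation p = 0.0016, adjusted 0.04). The 15 genes include tai, the tagged gene, and the comparison with matched lists was not run without it. With tai left out, the call by Fisher's exact test was kept.

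Genes of the Hippo growth-control pathway and its targets also had more peaks, with 9 of 24 (37.5%, 95% interval 18.8 to 59.4, odds ratio 7.03, Fisher's exact test, adjusted p = 0.000644). The strongest were at crb, a polarity gene (signal 408), Diap1, which blocks apoptosis (202), ex, an upstream member of the pathway (198), and ds, an atypical cadherin gene (165). Against lists matched on gene length and number of TSSs, which held 3.63 such genes on average, this call was lost (permutation p = 0.0068, adjusted 0.085). Of 25 lists, these 2 passed the threshold, and 7 had an unadjusted p under 0.05.

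Signalling and patterning genes had peaks without passing the threshold. Of the Notch pathway 5 of 17 genes had one, namely numb (signal 189), E(spl)m7-HLH (131), fng (119), mam (95.1) and neur (86.7) (Fisher's exact test, adjusted p = 0.0576). With the top peaks of replicate 1 alone the list passed with 8 genes (adjusted p = 0.000831), and with those of replicate 3 alone with 6 (0.0161), both by Fisher's exact test. Wing and leg disc patterning genes had 6 of 29, with dac (196), nkd (110), Dad (94.0) and sty (80.0), and an adjusted p of 0.0847 by Fisher's exact test. The list passed when summits anywhere in the gene body were counted, with 17 of 29 genes (adjusted p = 1.90e-08), as did nuclear receptors with 10 of 21 (0.000283) and the Notch pathway with 7 of 17 (0.00788), all by Fisher's exact test. Gene bodies were not matched on length, and near a TSS disc patterning and nuclear receptor genes did not pass against lists matched on length and number of TSSs (6 genes against a mean of 5.58, and 4 against 4.30), nor did Notch (5 against 1.59, permutation p = 0.0238, adjusted 0.198). Against matched lists, ecdysone response alone of the 25 passed.

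Among the other lists tied to hormones, ecdysteroid synthesis and uptake had 3 of 15 genes, with mld (signal 111), the ecdysone importer gene Oatp74D (96.7) and the sterol transport gene Npc1a (96.7). Nuclear receptors had 4 of 21 near a TSS, which were Eip75B, Hr39, EcR and Hr3. With replicate 3 alone 6 of the 21 had a peak and the list passed (odds ratio 4.70 compared with 2.75, Fisher's exact test, adjusted p = 0.0285). The bHLH-PAS family had 2 of 11, tai and sima (82.5), and juvenile hormone response and metabolism had 1 of 13, Kr-h1. Salivary glue and gland genes had 3 of 14, with fkh (471) and 1 peak between Sgs5 and Sgs5bis (90.8) that counted for both. The JAK-STAT pathway had 2 of 12, Socs36E (103) and Stat92E (86.5), and apoptosis and autophagy genes had 2 of 15, hid and Diap1 (202). Adjusted p-values for these lists by Fisher's exact test lay between 0.247 and 1.

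Markers of larval tissues showed no list past the threshold in these whole animals. Fat body markers had 2 of 13 (Adh, signal 132, with the summit nearest to the TSS of Adhr, and Desat1, 90.4) and 5 of 13 when gene bodies were counted (Fisher's exact test, adjusted p = 0.0406). Single genes had a peak among markers of neurons (elav, 243, of 15), muscle (Mef2, 102, of 17), cuticle and epidermis (grh, of 20), hemocytes (ush, 104, of 14) and trachea (tyn, 87.3, of 10), and none of 14 midgut markers did. Cytosolic ribosomal protein genes had 10 of 85, led by RpS12 (116), RpS27A (109), RpL7 (103) and RpS3A (103), and heat shock proteins had 1 of 15, Hsp27 (310). With replicate 1 alone, 5 of the 15 heat shock genes had a peak and the odds ratio turned from 0.831 to 4.84 (Fisher's exact test, adjusted p = 0.0349). None of 8 Hox genes and none of 15 chorion and vitelline genes had a summit within 1000 bp of a TSS, though Antp held 4 in its body or near it. None of 59 odorant, 60 gustatory or 60 ionotropic receptor genes had one near a TSS, each with an adjusted p of 0.0576 by Fisher's exact test. With the top peaks of replicate 1 alone these 3 receptor lists passed, each with an adjusted p of 0.0247 by Fisher's exact test. With those of replicate 3 alone none did (0.209, 0.0688 and 0.209, Fisher's exact test). With gene bodies counted, odorant (0 of 59, adjusted p = 0.00762) and gustatory receptors (1 of 60, 0.0406) passed and ionotropic receptors (2 of 60, 0.106) did not, by Fisher's exact test.

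**Figure D3:**
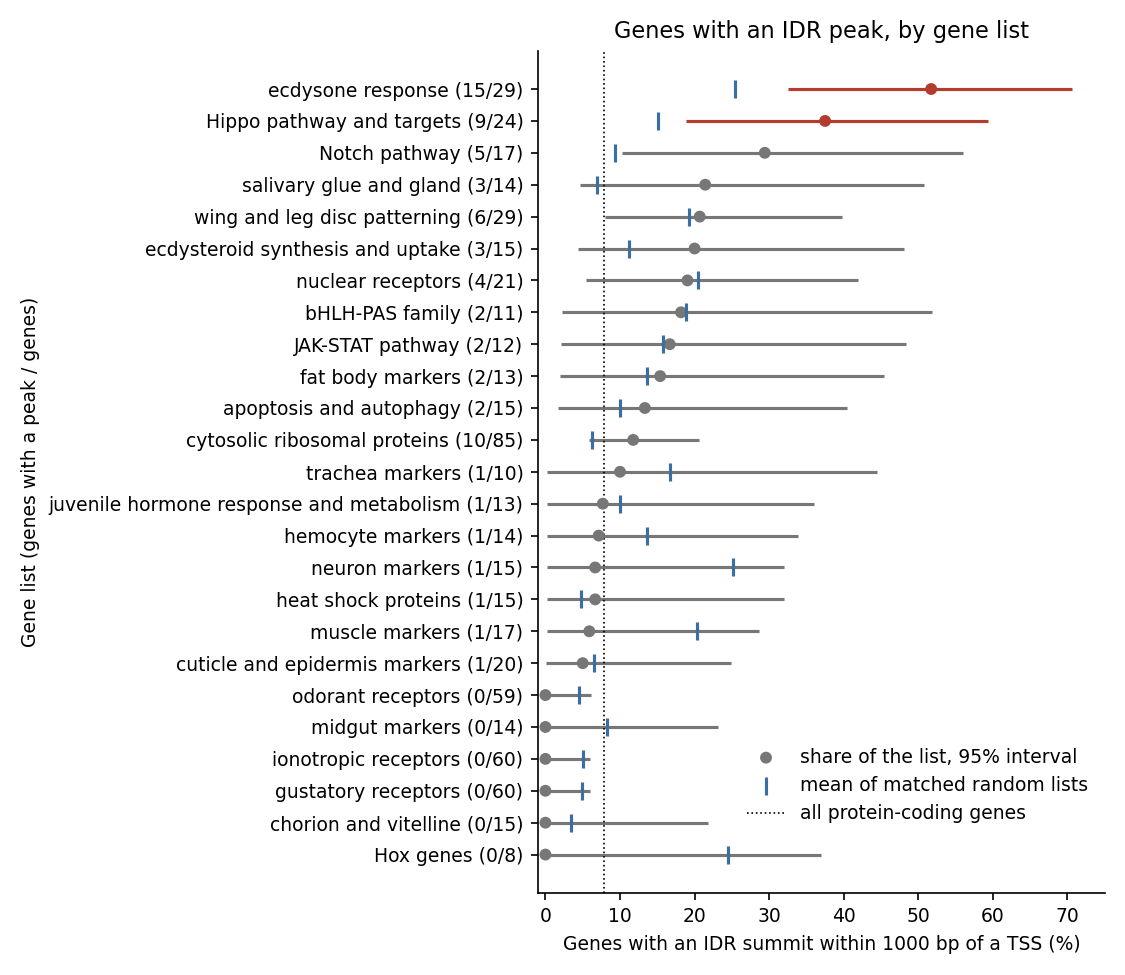
Percentage of the genes of each list with an IDR summit within 1000 bp of a TSS (x axis) for 25 lists (y axis, with counts), with 95% Clopper-Pearson intervals, the mean of matched random lists as a blue tick, and the share among all protein-coding genes (7.91%) as a dotted line. The lists past the threshold, in red, are ecdysone response (15 of 29) and Hippo pathway and targets (9 of 24).

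Sequence at the summits was richer than flanks in motifs of housekeeping promoters. The DNA replication-related element bound by DREF (TATCGATA) was present within 100 bp of 62 of 2543 summits and in 16 flanking windows (2.44% and 0.629%, McNemar's exact test, two-sided, adjusted p = 3.03e-06 over 20 motifs). Motif 1 of the M1BP factor (GGTCACACT) was at 21 summits and 5 flanks (0.826% and 0.197%, exact test, adjusted p = 0.0125). The forkhead motif was at 15.7% of summits and 10.9% of flanks (exact test, adjusted p = 4.01e-06), and the GATA motif at 18.6% and 15.5% (exact test, adjusted p = 0.0161). The ETS motif (0.354% and 1.22%) and the E-box CAGCTG (7.27% and 9.36%) were less frequent at summits (exact tests, adjusted p = 0.00453 and 0.0255).

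The EcR-USP palindrome occurred at 1 summit and in 5 flanks (McNemar's exact test, adjusted p = 0.365), and the nuclear receptor motif AGGTCA at 92 and 124 (exact test, adjusted p = 0.0849). The motif CACGCG, to which tai binds with juvenile hormone receptors, was at 3.70% of summits and 3.54% of flanks (exact test, adjusted p = 0.824). GC content was 35.9% at summits, 40.8% in flanks and 34.5% at lower-ranked regions, so the flanks were not matched in composition. The DRE call alone was kept in all 8 alternatives, against permuted motifs at an unadjusted permutation p of 0.0236. The others were lost in at least 3 of them, and the CAGCTG difference turned to the opposite direction against lower-ranked regions (log2 ratio 0.48, Fisher's exact test, adjusted p = 0.000118). GATA was at 18.4% of lower-ranked regions and forkhead at 14.2%, and forkhead did not pass against permuted motifs (permutation p = 0.381). Against windows matched on GC and TSS distance, which the flanks were not, the DRE log2 ratio fell from 1.92 to 0.91 (Fisher's exact test, adjusted p = 0.000367). That of Motif 1 fell from 1.97 to 0.63 and its call was lost (exact test, adjusted p = 0.188). In that comparison the GAGA motif passed (log2 ratio 1.28 compared with 0.10 against flanks, Fisher's exact test, adjusted p = 1.06e-12), as did CACGCG (log2 ratio 0.69, exact test, adjusted p = 0.000445). The CA repeat, included as a low-complexity control, passed too (log2 ratio 0.53, exact test, adjusted p = 0.00182), so a pass there does not single out a factor. AGGTCA was less frequent at summits there (log2 ratio -0.41, exact test, adjusted p = 0.0239), and also with the top peaks of either replicate alone (exact tests, adjusted p = 0.00757 and 0.0430).

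By arm, 3L and the small chromosome 4 held more IDR peaks than their share of protein-coding genes, and 2R and 3R fewer. 3L, which carries Eip75B, Eip74EF and Eip63F-1, held 625 peaks, or 24.3% (95% interval 22.7 to 26.1) compared with 19.6% of genes (exact binomial test, two-sided, adjusted p = 3.02e-08). Chromosome 4 held 37, or 1.44% compared with 0.574% (exact binomial test, adjusted p = 2.20e-06). 2R held 16.4% compared with 20.5% (exact binomial test, adjusted p = 6.20e-07) and 3R held 566 peaks, 0.899 times its share (adjusted p = 0.00498, exact binomial test). 2L held 539 peaks, 1.10 times its share (exact binomial test, adjusted p = 0.0154), and X held 14.8% compared with 15.7% (exact binomial test, adjusted p = 0.176). Against arm length, the excess of chromosome 4 was smaller (1.44% of peaks on 1.01% of the length, exact binomial test, adjusted p = 0.0369). X passed with fewer peaks (14.8% on 17.6% of the length, exact binomial test, adjusted p = 0.000275). Against gene share, the X difference passed when replicate 3 alone was used (13.4%, exact binomial test, adjusted p = 0.00113). Neighbouring peaks are not independent, so these p-values are too small. Without the peaks within 10 kb of tai the 2L difference was lost (exact binomial test, adjusted p = 0.288), and among the 50% of peaks with the highest signal chromosome 4 held 0.701% (exact binomial test, adjusted p = 0.491).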

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

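The tests of the mitochondrial peaks and of the peaks in tai were chosen only after those results were seen.

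Outside the chromosome arms, 24 IDR peaks lay on the mitochondrial genome on dm6. They are given here because no comparison on the arms used them, and since the control was not analysed here, their number was not tested. The 8 strongest peaks of the whole list were among them, with the highest signal (3140) at mt:Cyt-b (interval 9729 to 12727, summit 10802) and others at mt:CoIII (2916) and mt:CoII (2436). Reads from the many copies of this genome are a candidate explanation. The peaks covered 63.0% of its 19524 bp and had summits in 9 of its 13 protein-coding genes, as that explanation needs. Signal is given relative to a control that was not analysed here, so this coverage cannot decide the question. On dm3, 4 mitochondrial IDR peaks were listed, with a highest signal of 147, and the cause of that gap was not tested. No biological explanation was tested.

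On dm3, 11 IDR peaks lay on contigs outside the arms and the mitochondrial genome, and are given for the same reason without a test. The dm6 IDR list held 0 such peaks.

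tai, the tagged gene, held 31 IDR summits, more than any other gene. Gene length did not account for it, since its 3.63 summits per 10 kb lay at percentile 99.7 of 307 protein-coding genes of 50000 bp or more (2.39 in Eip74EF, the next). An extra copy of the tagged gene is a candidate explanation that stays open. With the signals of the tai peaks divided by 2, as for 2 extra copies, 7 of the 31 stayed above the lowest IDR signal. This was fewer than the 22 of Eip75B, whose signals were not divided. The lowest IDR signal on the arms was 65.2 and the 75th percentile 125, so dividing by 2 removes most peaks whatever the copy number. The outcome therefore cannot decide the question. That test takes signal to scale with copy number, the extent of the tagged construct is not given in the sources used here, and the last 16538 bp of tai held no IDR summit but a top peak of replicate 1 (summit 9235671, signal 112), while binding of the protein to its own gene was not tested.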

How the results depend on the processing

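Alternatives chosen after seeing the data are named in the account of processing. The promoter share stayed above its expected value in all 9 alternatives (23.5% to 43.5%). Ecdysone response kept its call in 9 of 9, DRE in 8 of 8, and arms 2R, 3L and 3R in 5 of 5. The highest odds ratio of ecdysone response was 20.2, with gene bodies, which were not matched on length. Against matched lists its count was 2.03 times their mean, which is not an odds ratio. No paired analysis was possible because there is 1 group. The 50% of peaks with the highest signal numbered 1296, gave a rho of 0.51, and left 3 motifs and 3 arms past the threshold (6 and 5 in the main results), with fewer peaks tested. Replicate overlap was 44.2% with reciprocal overlap of 50%, 43.3% with summits within 100 bp, 58.3% for the top 50% of peaks and 53.7% for the whole lists. The number of gene lists past the threshold, 2 in the main result, was 8 with gene bodies, 1 against matched lists, 5 among genes with any pooled region, and 4 to 7 when either replicate was left out. For heat shock proteins the odds ratio of 0.831 ranged from 0.836 to 4.84 when either replicate was left out, and turned with replicate 1 alone. The number of motifs past the threshold, whichever they were, was 6 in the main result, 2 with windows of 50 bp either side and 3 to 5 when either replicate was left out. It was 6 against windows matched on GC, where only forkhead and DRE were among those of the main result. Against permuted motifs 1 passed, DRE, at an unadjusted permutation p of 0.0236, a laxer rule than the adjusted p of the other alternatives. The log2 ratio of CAGCTG turned to 0.27 against windows matched on GC and 0.48 against lower-ranked regions. The cause was not tested. For permuted motifs the value compared was the log2 ratio against flanks minus the mean of the permutations. It was 0.0522 for CAGCTG (ratio -0.363, permutation p = 0.824) and -0.0818 for GATA (ratio 0.260, permutation p = 0.493). Neither ratio itself turned there. In all, 208 of 225 gene list values, 123 of 160 motif values and 31 of 36 arm values kept their side of the threshold, whatever the change in size. The dm3 arm shares, untested, lay within the 95% interval. A turn in direction counted only where the main result or the alternative passed, so values that passed in neither could turn and still count as kept. Only 2 gene lists and 6 motifs passed in the main result, so most of these values concern lists and motifs that did not. Of 171 peak ranks of named genes, 104 differed from the pooled rank by no more than 1 SD of the ranks in the replicates. That SD is wide where the replicates differ, and genes without a peak gave no rank. The 171 include ranks with summits limited to 500 bp from a TSS. These ranks repeat the pooled rank wherever the summit already lay that near, so 104 overstates agreement between replicates.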

Other observations

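Beyond the genes with the most summits, IDR peaks gathered in a few windows of 100 kb. Of 1342 windows 578 held no summit, and the median was 1. The fullest held 22 and covers the 5' part of tai (2L, 9100001 to 9200000). A window with tara and gish (3R, 16200001 to 16300000) held 19, and the one with most of EcR (2R, 6100001 to 6200000) held 17. One with hng3 and CG13896 (3L, 700001 to 800000) held 16, and one with heca (3R, 30200001 to 30300000) held 15. Windows with Eip75B held 15 and 14, one with sbb 14, one with Eip74EF 14, and one with E2f1, a cell cycle regulator gene, and InR, the insulin receptor gene, 14 (3R, 21600001 to 21700000). A window with tkv, a BMP receptor gene, and vri, an ecdysone-responsive bZIP gene, held 13 (2L, 5200001 to 5300000), as did the window next to the fullest, with the rest of tai.

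The 20 motifs were split by distance, a division chosen after the data were seen. DRE was at 6.83% of summits within 500 bp of a TSS and 0.293% of the others, and Motif 1 at 2.16% and 0.176%. Others differed too, with CACGCG at 5.64% and 2.75%, CAGCTG at 9.71% and 6.09%, and the STAT motif at 3.96% and 7.14%. Promoters without a peak were not part of this split, so it does not tell motifs of bound promoters from those of promoters at large.

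For IDR peaks near ecdysone response genes, the matched lists were planned before the data were examined, the test of the weakest regions was chosen after the enrichment but before its own value was seen, and the other tests after. Lists matched on gene length and number of TSSs held 7.38 genes with a peak on average, and 0.0700% of 10000 held 15 or more. Matching was by 10 bins of length and by bins of TSS number. The bin of the longest genes is wide, so effects of length within bins were not excluded. A general nearness of listed regions was tested with the weakest pooled regions, as many as the IDR peaks. They gave an odds ratio of 3.47 against 12.6 for the IDR peaks (95% interval 6.08 to 26.2). The interval of the weakest regions reached 11.5 and overlapped that of the IDR peaks, so this test cannot exclude nearness. The list was also tested among genes with any pooled region near a TSS. It still passed there, with a lower odds ratio of 4.87 (Fisher's exact test, adjusted p = 0.00532), so nearness may account for part of the enrichment. Those genes were not matched on length or number of TSSs, so nearness and length were not tested together. Direct contact through EcR-USP palindromes stays open, since the strict consensus was too rare to decide (0 of 138 peaks at these genes, 0 of their flanks and 1 of 2429 other peaks) and looser sites were not searched.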
